A study of Homo sapiens and Mus musculus with 81 samples.

How the data were processed

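Expression was profiled on 81 one-colour oligonucleotide arrays of a custom Affymetrix-type design, 56 of human cells and 25 of mouse cells or tissue. HUH7 and PLC/PRF/5 are human liver cancer cell lines, and Hepa1-6 is a mouse hepatoma line. Per the labels' protocols, cells in 6-well plates were transfected with 10 nM siRNA in Lipofectamine RNAiMAX, or mock transfected, and collected after 6, 12, 24 or 48 h (in PLC/PRF/5, 6, 12 or 48 h). Mice received 3 mg/kg siRNA in a lipid nanoparticle, and livers were taken after 3 d. The 32 HUH7 and 24 PLC/PRF/5 arrays covered 8 treatments: the siRNAs APOB-Hs1, APOB-Hs2, APOB-Hs3, APOB-Hs4, Apob-Mm1, Apob-Mm2 and RAD18, and mock. The 16 Hepa1-6 arrays covered APOB-Hs1, APOB-Hs3, APOB-Hs4 and mock. The 9 liver arrays covered the same 3 siRNAs with 3 livers each. Groups were taken from the labels alone. There was 1 array per treatment and time in the cell lines, so the time points stood in for replicates.

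Each deposited value was an intensity per probe set, summarised by the authors with RMA (robust multi-array average) per the submitters' processing notes. The version of that tool and the genome build behind the probes are not given in the sources used here. The values were right skewed and on a linear scale, and their log2 was taken here. No detection calls were used, and no column came from another series. Median intensities ran from 31.75 to 35.39 over the human arrays and from 19.73 to 22.55 over the mouse arrays. The number of arrays limits the precision of each comparison.

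Probe sets were named from the array annotation. Of 43483 human probe sets, 25919 carried 1 gene symbol, 0 carried several and 17564 carried none. Human symbols were brought up to date from RefSeq gene names, where 21630 probe sets had a current symbol, 2085 were updated by transcript accession, 2143 by an older symbol, and 61 were kept as given. Of 43681 mouse probe sets, 30342 carried 1 symbol, 0 several and 13339 none, and mouse symbols were used as the annotation gives them. Probe sets without a symbol were left out of every test. Each gene was represented by its probe set with the highest mean in that system, which left 17836 human and 21931 mouse genes. Human and mouse genes were paired by symbol without regard to case, which matched 12205. No coordinates are given, since the build is unknown.

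Models were fitted with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8). In each cell line the model had treatment and time as factors. Contrasts were each siRNA minus mock, the mean of all siRNAs minus mock and, in the human lines, the mean of the 4 siRNAs named for human APOB minus the mean of Apob-Mm1, Apob-Mm2 and RAD18. In liver each siRNA was compared with the mean of the other 2, since the samples listed hold no untreated liver. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast (two-sided). A difference in response between HUH7 and PLC/PRF/5 was tested as a limma interaction over 6, 12 and 48 h. The likeness of an siRNA's signature in a pair of systems was the Pearson correlation across genes of its difference from the mean of the other siRNAs, tested with a one-sided exact permutation of the siRNA names. Numbers of genes lower in both systems were compared with independence by a one-sided Fisher's exact test, adjusted over the siRNA combinations of a pair. The course over time was read in genes called lower in the other human line, with a two-sided exact sign-flip permutation test over siRNAs.

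The 21 gene lists were written before the data were examined, as were the design and the alternatives tried, except 3 alternatives added later. They covered cholesterol synthesis and SREBP2 targets, fatty acid and triglyceride synthesis, lipoproteins, fatty acid oxidation and PPARA targets, the unfolded protein response, the interferon response, the acute phase, the cell cycle, p53 targets, small RNA machinery, miR-122 targets, let-7 targets, xenobiotic metabolism, hepatocyte genes, and markers of Kupffer cells, stellate cells, liver endothelial cells, lymphocytes, neutrophils, cholangiocytes and red blood cells. Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. Some liver markers are also transcribed by other cell types, so a list is not a measure of 1 cell type.

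Genes were named by rule. APOB and RAD18 were always named. For each siRNA in a human line, the 3 most negative and the 1 most positive genes were named, among those past the test with the same sign at every time. In Hepa1-6 and liver these numbers were 5 and 3, and for contrasts over several siRNAs 5 and 5. Up to 4 members past the test were named per list, and 3 genes per siRNA among those lower in both systems of a pair. The text prints a part of them and says where a gene was chosen after its values were seen.

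The alternatives were quantile normalization, the mean of all probe sets of a gene, leaving out the dimmer part of the genes, no time term, a fit of 1 siRNA with mock alone, the other siRNAs as the reference, limma with trend and robust settings, leaving out each time point or liver, the liver number as a block, single siRNAs as the reference in liver, Spearman correlation and the estimated correlation of camera. An analysis of hexamers in 3′ untranslated regions was planned and not run, since the references hold no transcript sequences. Unnamed probe sets were left out because no gene could be read from them.

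The pipeline was tested on simulated data made from the same layout. At a simulated log2 difference of 0.5, 1 and 2, the share of altered genes called was 88.1%, 100% and 100% in HUH7, 59.7%, 92.5% and 100% in PLC/PRF/5, 71.6%, 98.5% and 100% in Hepa1-6, and 71.6%, 92.5% and 100% in liver. The share of false calls was 6.80%, 1.75%, 5.26% and 2.76%. The simulated differences were the same at every time and the noise was independent, while real differences in the cell lines grew with time. Recovery in the real data can therefore be lower. The adjusted p also depends on how many other genes change in a contrast. APOB at -2.44 with Apob-Mm1 in PLC/PRF/5, where 0 genes were called, was missed. APOB at -2.54 with APOB-Hs3 there, where 52 genes were called, passed, so growth with time alone does not account for the miss. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.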

Results

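Messenger RNA was measured on 81 arrays in 2 human liver cancer lines, 1 mouse hepatoma line and mouse liver after siRNA. HUH7 had 32 arrays and PLC/PRF/5 had 24, each with 8 treatments, Hepa1-6 had 16 arrays with 4 treatments, and liver had 9 arrays with 3 siRNAs in 3 livers each. Every array correlated with another of its system at r of at least 0.99. The 4 arrays with the widest residual spread around the fitted model were PLC/PRF/5 with APOB-Hs2 at 48 h (SD 0.198 on the log2 scale), PLC/PRF/5 with APOB-Hs4 at 48 h (0.186), HUH7 with APOB-Hs1 at 12 h (0.167) and liver 1 of APOB-Hs4 (0.166). Values below are log2 differences with their SE and limma's adjusted p, which rests on the spread of arrays around the fitted model. In liver that is only the spread between samples. In the cell lines time points stand in place of replicates, so it also holds any change of an effect with time. Medians and counts of gene lists cover named genes on the array.

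The first question was how far each siRNA lowered its target. APOB encodes the structural protein of very low and low density lipoproteins. In HUH7, APOB fell with all 4 siRNAs named for it, to -2.04 from mock with APOB-Hs1 (SE 0.261, adjusted p = 9.6e-06), -2.51 with APOB-Hs2 (7.57e-06), -1.69 with APOB-Hs3 (0.000486) and -2.31 with APOB-Hs4 (2.17e-05). In PLC/PRF/5 APOB fell to -2.67 with APOB-Hs1 (SE 0.407, adjusted p = 0.00184), -3.19 with APOB-Hs2 (0.00042), -2.54 with APOB-Hs3 (0.00762) and -3.27 with APOB-Hs4 (0.000263). The difference between the lines did not pass the test over all genes for any siRNA (lowest adjusted p 0.718). As HUH7 minus PLC/PRF/5 it ran from 0.80 to 1.23 with these 4 siRNAs (SE 0.551), each with the deeper fall in PLC/PRF/5. It was 1.36 with Apob-Mm1, 1.15 with Apob-Mm2 and 0.10 with the RAD18 siRNA. All share the same mock arrays, so a lack of calls does not show that the lines are alike. APOB with the siRNAs named for mouse Apob differed from mock by -1.27 (Apob-Mm1, adjusted p = 0.192) and -0.81 (Apob-Mm2, 0.14) in HUH7 and by -2.44 (0.156) and -1.82 (0.102) in PLC/PRF/5, none past the test over all genes. Against the RAD18 siRNA in place of mock, a comparison chosen after the values were seen, APOB was lower with Apob-Mm1 in HUH7 (-1.28, adjusted p = 0.00748) and with both in PLC/PRF/5 (-2.40, 0.00916, and -1.78, 0.037), and with Apob-Mm2 in HUH7 it was at -0.82 (0.0733). These sizes were close to those against mock, so the calls differed through the adjustment over all genes and not through a larger fall. Limma's unadjusted p against RAD18 was 4.1e-05 for Apob-Mm1 and 0.00412 for Apob-Mm2 in HUH7, and 1.08e-05 and 0.000316 in PLC/PRF/5. With the RAD18 siRNA itself APOB stood at 0.01 from mock in HUH7 (0.994) and -0.04 in PLC/PRF/5 (0.999). Without the 6 h arrays, APOB with the mouse-named siRNAs passed the test at -1.58 (6.1e-05) and -1.12 (0.000292) in HUH7 and at -3.05 (0.000817) and -2.51 (0.00148) in PLC/PRF/5. The calls for APOB-Hs3 in HUH7 were lost without 24 h (-1.53, 0.0837) or 48 h (-1.42, 0.0561), those for all 4 human-named siRNAs in PLC/PRF/5 were lost without 12 h (adjusted p 0.378 to 1, at -3.16 to -2.42), and those for APOB-Hs1 (-2.26, 0.0781) and APOB-Hs3 (-1.83, 0.188) were lost without 48 h.

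RAD18 is a ubiquitin ligase of post-replication repair. RAD18 fell by 1.98 with its siRNA in HUH7 (SE 0.113, adjusted p = 1.1e-11) and was at -3.25 in PLC/PRF/5 (SE 0.239, 4.48e-07). With the other siRNAs RAD18 differed from mock by -0.03 to 0.22 in HUH7 and by -0.47 to 0.01 in PLC/PRF/5, none past the test. In Hepa1-6, mouse Apob fell with the 3 siRNAs used there, to -2.64 with APOB-Hs1 (SE 0.235, adjusted p = 4.67e-05), -2.32 with APOB-Hs3 (0.000771) and -2.44 with APOB-Hs4 (0.000202). At 48 h APOB stood at 13.5% to 20.9% of mock with the 4 human-named siRNAs in HUH7, at 6.10% to 8.84% in PLC/PRF/5 and at 9.79% to 11.8% in Hepa1-6, and with Apob-Mm1 and Apob-Mm2 it stood at 33.1% and 41.9% in HUH7 and 10.2% and 11.3% in PLC/PRF/5. Livers had no untreated reference, and mean log2 Apob was 11.20 ± 0.06 with APOB-Hs1, 11.41 ± 0.27 with APOB-Hs3 and 10.73 ± 0.17 with APOB-Hs4 (SD, n = 3). None of the liver differences passed the test (0.13, 0.45 and -0.57 from the mean of the other 2, adjusted p 0.69, 0.388 and 0.099).

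**Figure D1:**
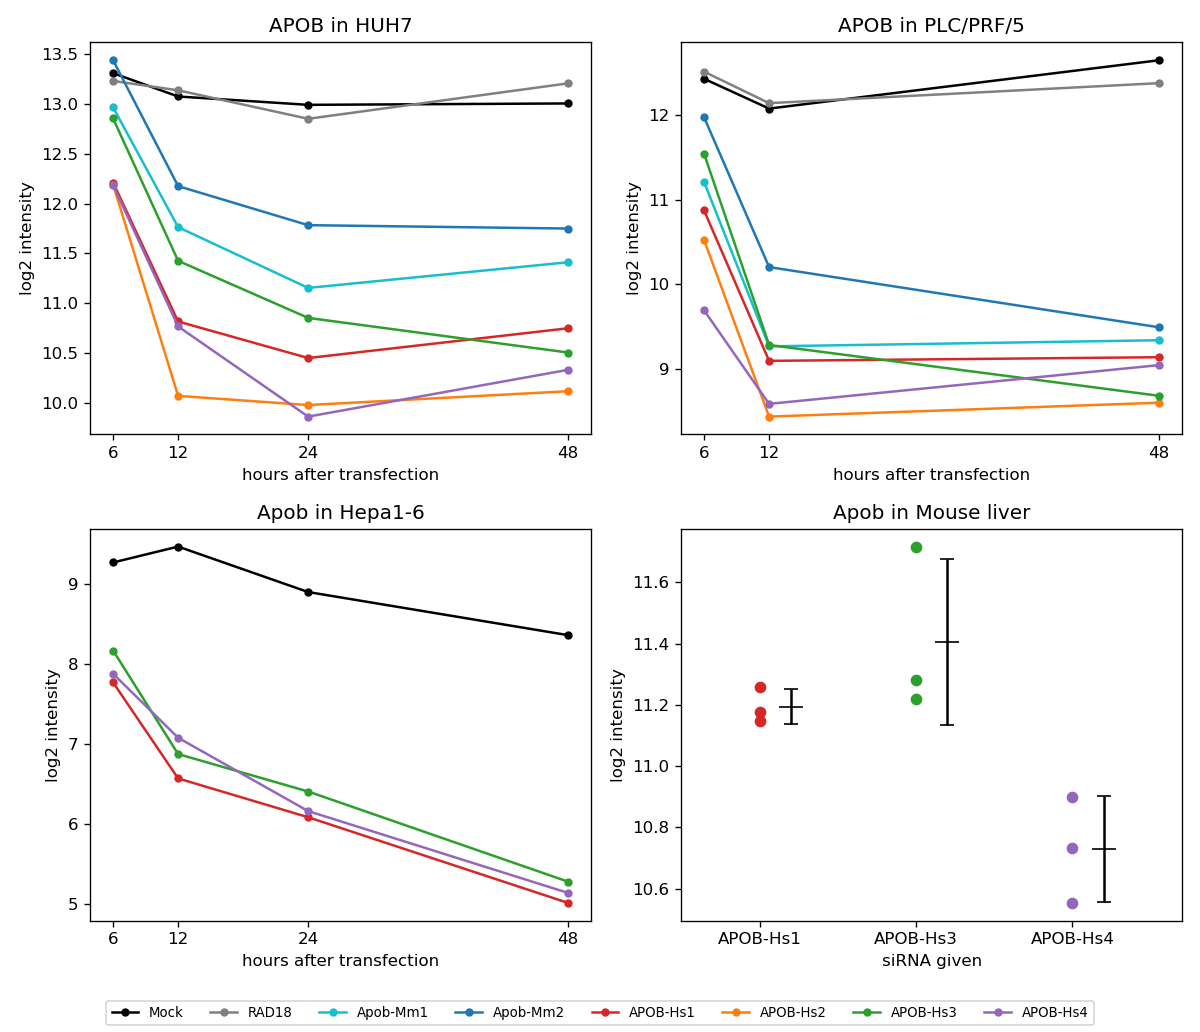
APOB log2 intensity per array against hours after transfection in HUH7, PLC/PRF/5 and Hepa1-6, one line per treatment, and in each mouse liver with the group mean and SD. Mock averaged 13.10, 12.38 and 9.01 in the 3 lines, and by 48 h each siRNA named for human APOB lay below the mock line.

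The next comparison asked which other transcripts each siRNA moved in HUH7. With APOB-Hs1 these were led by BLOC1S6, a subunit of a complex that builds lysosome-related organelles (-2.32, SE 0.16, adjusted p = 3.45e-10), and by GALNT5, which starts O-glycosylation of mucin-type proteins (-2.21, 4.97e-09), while the potassium channel gene KCNJ8 rose by 0.77. With APOB-Hs2 the kinetochore gene SKA2 fell by 1.35 (0.000228) and ARMCX3 fell by 1.24. With APOB-Hs3 DENND10 fell by 1.82 (5.34e-07) and HMOX1, which encodes heme oxygenase 1, fell by 1.66 (1.72e-10). With APOB-Hs4 FYCO1, an adaptor in autophagosome transport, fell by 1.29, WASHC4 of the endosomal WASH complex fell by 1.24 (2.17e-05), and the integrin gene ITGB8 rose by 1.04. With Apob-Mm2 the transporter gene ABCC5 fell by 1.90 (2.51e-12), the retinol dehydrogenase gene RDH10 fell by 1.42 and XPO5, the nuclear exporter of microRNA precursors, fell by 1.26 (1.34e-05). With the RAD18 siRNA EREG, an EGF-family ligand, fell by 1.62 (2.89e-05) and POLR3G, a subunit of RNA polymerase III, fell by 1.32.

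Of 17836 genes, 452 changed with APOB-Hs1 (324 lower, 128 higher), 424 with APOB-Hs2 (214, 210), 400 with APOB-Hs3 (273, 127), 283 with APOB-Hs4 (96, 187), 231 with Apob-Mm2 (136, 95) and 168 with RAD18 (131, 37). Quantile normalization turned the APOB-Hs4 balance to 161 lower and 135 higher. With Apob-Mm1 limma called 0 genes, with 631 at an unadjusted p under 0.05 and 0 to 4 called under the alternatives tried. Those 631 are a smaller share of the genes than the 0.05 expected with no change. The ribosomal protein gene RPL41 was the highest-ranked rise with APOB-Hs2 (1.09, adjusted p = 0.000113) and APOB-Hs3 (0.73, 0.00652). Counts fell when 24 or 48 h was left out, in fits with fewer arrays: without 24 h they were 105, 22, 10, 7, 13 and 24 in the order above, and without 48 h 204, 118, 50, 24, 18 and 86. No called gene took the opposite sign in these fits, and why the counts fell was not tested. Without 12 h they were 255, 120 and 158 for the first 3 and 105 for Apob-Mm2, without 6 h APOB-Hs3 had 701 and Apob-Mm1 had 3, and without the widely spread APOB-Hs1 array of 12 h APOB-Hs4 had 512 and Apob-Mm1 had 1.

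The mean of the 7 siRNAs was then set against mock in HUH7. KLF2, a transcription factor (-0.71, SE 0.134, adjusted p = 0.0165), the Notch target HEY1 (-0.57), FOXQ1 (-0.52) and HMOX1 (-0.44, 0.0125) were lower. RPL41 (0.70, 0.0065), GTF2A1, a subunit of the general transcription factor TFIIA (0.53, 0.00097), and the growth-restraining or pro-apoptotic genes BTG2 (0.37, 0.0181) and BCL2L11 (0.36, 0.0119) were higher. The HMOX1 mean rested mainly on APOB-Hs3 (-1.66), and that gene was not lower with APOB-Hs1. In all, 36 genes changed, 10 lower and 26 higher, or 13 and 21 after quantile normalization. Of 23 genes of the unfolded protein response, limma called 0 over all genes, 2 rose and 4 fell when adjusted over the list alone, and 2 and 6 did so at an unadjusted p under 0.05. The median was -0.05 and the list was lower by camera (adjusted p = 0.0304), which was lost at adjusted p = 0.556 with an estimated correlation. Of 21 genes of xenobiotic metabolism 2 fell over all genes, HMOX1 and SRXN1 (-0.36), and 1 rose and 4 fell adjusted over the list alone, without a call for the list (0.108). CDC25A of the cell cycle list rose by 0.22. The count was 0, 3 and 7 without 24, 12 and 48 h (unadjusted, the full set gave 1687), and 68 without the APOB-Hs1 array of 12 h.

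The 4 siRNAs named for human APOB were then set against the other 3 in HUH7. TNRC6B, a partner of the Argonaute proteins in silencing by small RNAs, was lower by this measure (-0.78, SE 0.073, adjusted p = 2.82e-07), as were APOB (-1.45), GALNT5 (-0.72) and NSF, an ATPase of membrane fusion (-0.59). Among higher genes were RAD18 (0.77, 2.34e-08), ABCC5 (0.55), BTG3 (0.53), the cholesterol ester hydrolase gene NCEH1 (0.48) and E2F3 (0.44). TNRC6B stood at -0.69 to -0.10 from mock with the 4 human-named siRNAs, past the test only with APOB-Hs3. It stood at 0.225 to 0.562 from mock with the other 3, so part of the difference came from the reference side. Other members of this contrast rested mainly on 1 siRNA: GALNT5 (-2.21) and NSF (-2.0) on APOB-Hs1, ABCC5 on its fall with Apob-Mm2, and RAD18, BTG3 (-0.98) and NCEH1 (-1.02) on their falls with the RAD18 siRNA. In all 700 genes changed, 320 lower and 380 higher. Of 14 genes of small RNA machinery, 1 was higher, XPO5 (0.43), and 2 were lower, TNRC6B and DICER1 (-0.39, 0.00134), or 2 and 3 adjusted over the list alone. XPO5 stood at -0.03 to 0.08 from mock with the human-named siRNAs and at -1.26 with Apob-Mm2, and DICER1 rested mainly on APOB-Hs1 (-0.95). The lowest list p by camera was 0.0695, shared by the cell cycle, whose members CCNE1 (0.28), E2F1 (0.17) and PCNA (0.12) were higher, fatty acid oxidation, whose members CREB3L3 (-0.40, from -1.23 with APOB-Hs3) and SLC25A20 (-0.20) were lower, and lipoproteins and their assembly, of whose 26 genes limma called 0 over all genes, 3 unadjusted. INSIG1, the sterol-sensing partner of SREBP, was the 1 changed gene of 21 in cholesterol synthesis (-0.36, 4.69e-06). Without 24 h the count was 53 and without 48 h it was 119.

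The same comparisons were made in PLC/PRF/5. With APOB-Hs1 NSF fell by 2.74 (SE 0.293, adjusted p = 4.98e-05) and BLOC1S6 fell by 2.52 (5.98e-07). With APOB-Hs2 SKA2 fell by 2.01 (0.00705) and the splicing factor gene SFPQ fell by 1.78 (0.000188). With APOB-Hs3 DENND10 fell by 1.99 (3.14e-05) and HMOX1 fell by 1.78 (0.000103), and with APOB-Hs4 the integrin-linked kinase gene ILK fell by 2.52 (0.000134) and WASHC4 fell by 1.83 (4.25e-08). With Apob-Mm2 RDH10 fell by 2.28 (3.79e-05), XPO5 fell by 1.80 (0.000126) and ABCC5 fell by 1.73 (5.26e-09). With the RAD18 siRNA TMEM106C fell by 1.62 (0.00496) and EREG fell by 1.60 (0.00206). Few genes rose, among them the receptor gene NR6A1 with APOB-Hs2 (0.82, 0.0376), the mucin gene MUC4 with APOB-Hs3 (0.62, 0.0358) and the deubiquitinase gene YOD1 with Apob-Mm2 (0.79, 0.0146).

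Changed genes numbered 107 with APOB-Hs1 (94 lower, 13 higher), 63 with APOB-Hs2 (54, 9), 52 with APOB-Hs3 (51, 1), 36 with APOB-Hs4 (35, 1), 25 with Apob-Mm2 (24, 1) and 42 with RAD18 (42 lower). With Apob-Mm1 limma called 0 genes, 358 at an unadjusted p under 0.05, and 0 or 1 under the alternatives. Those 358 are again a smaller share of the genes than the 0.05 expected with no change. For the 7 siRNAs on average only APOB changed (-2.28, SE 0.308, adjusted p = 0.00843). Of 21 p53 targets limma called 0 over all genes and 0 adjusted over the list alone, with 2 higher at an unadjusted p under 0.05, and the list was higher by camera (median 0.086, adjusted p = 0.0127), which was lost at adjusted p = 0.244 with an estimated correlation. Xenobiotic metabolism was lower (median -0.06, 0.0245, lost at adjusted p = 0.362 with an estimated correlation and at 0.0744 after quantile normalization), with 1 of 21 genes lower adjusted over the list alone, 0 over all genes and 3 unadjusted. The 4 human-named siRNAs against the others gave 70 genes (48 lower, 22 higher), led by TNRC6B (-1.03, SE 0.125, adjusted p = 0.000491), the anion channel subunit gene LRRC8B (-0.90), NSF (-0.88) and FRYL (-0.78) on the lower side besides APOB (-1.48), and by RAD18 (0.87), XPO5 (0.53), E2F3 (0.51) and SAMD4A (0.50) on the higher side. TNRC6B stood at -1.13 to -0.53 from mock with the 4, past the test with APOB-Hs2 and APOB-Hs3, and at 0.054 to 0.315 with the others. NSF (-2.74) and FRYL (-2.20) rested on APOB-Hs1, and LRRC8B on APOB-Hs2 (-1.55) and APOB-Hs3 (-1.21). XPO5 rested on Apob-Mm2 (-1.80) and SAMD4A mainly on the RAD18 siRNA (-0.84). CREB3L3 was lower there as well (-0.43, 0.0487), with -1.72 for APOB-Hs3, and no list passed (lowest adjusted p 0.101). Without 12 h the counts of the siRNAs with calls were 4, 0, 0, 1, 1 and 1, and without 48 h they were 49, 39 and 20 for APOB-Hs1 to APOB-Hs3 and 10 for Apob-Mm2, while the contrast of human-named siRNAs fell to 0 and 10 and the average to 0 in both cases. Without 6 h APOB-Hs2 had 105, APOB-Hs4 18, Apob-Mm2 49 and Apob-Mm1 1, and without the widely spread arrays of APOB-Hs2 and APOB-Hs4 at 48 h APOB-Hs1 had 168, APOB-Hs3 111, Apob-Mm2 48 and RAD18 69.

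In Hepa1-6 the comparison asked what 3 of these siRNAs moved in mouse cells. With APOB-Hs1 Bivm, a gene of unknown function, fell by 2.37 (SE 0.158, adjusted p = 5.79e-06), Acbd5 of the peroxisome membrane fell by 1.30, the spectrin gene Spna2 fell by 1.29 and Nomo1 of the endoplasmic reticulum fell by 1.23 (0.000563). With APOB-Hs3 Lims1, which encodes a binding partner of ILK, fell by 1.07 (0.0013), the kinase genes Prkx and Mapk6 fell by 1.02 and 0.96, and Mylip, a ubiquitin ligase for the LDL receptor, rose by 0.46. With APOB-Hs4 Ilk fell by 1.88 (3.59e-05), Wdr55 fell by 1.25, Atg9a of autophagosome formation fell by 1.24 (0.00344) and the utrophin gene Utrn fell by 1.14, while Cd300lb rose by 1.28. Lipogenic Elovl6 (-0.84, 0.00589) and Scd1 (-0.61, 0.00477) were lower with APOB-Hs1, Cxcl10 was lower with APOB-Hs3 (-0.81, 0.00464), and Btg2 was higher with APOB-Hs4 (0.72, 0.0147).

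Of 21931 genes, 165 changed with APOB-Hs1 (139 lower, 26 higher), 125 with APOB-Hs3 (115, 10) and 259 with APOB-Hs4 (147, 112). The average of the 3 siRNAs changed 8 genes, 7 lower, with Apob (-2.47, 4.66e-05), Bivm (-0.92, 0.0276), Lims1 (-0.63) and Trp53inp1 (-0.51), and 1 higher, Rdm1 (0.84, 0.0497). The Bivm mean rested mainly on its fall with APOB-Hs1 given above, so a call for the average is not a response to all 3. For this average the small RNA machinery was higher (14 genes, median 0.081, adjusted p = 0.0392, lost at adjusted p = 0.318 with an estimated correlation and at 0.0906 after quantile normalization), with 4 higher and 1 lower adjusted over the list alone, and limma called 0 over all genes, 5 unadjusted. With APOB-Hs1 the interferon response was lower (29 genes, median -0.097, adjusted p = 0.0194, lost at adjusted p = 0.293 with an estimated correlation), with 1 lower over all genes, Ifit2 (-0.42, 0.0413), and 3 adjusted over the list alone. No list passed with APOB-Hs3 (lowest adjusted p 0.0518, cell cycle) or APOB-Hs4 (lowest 0.127). Without 12 h the counts were 37, 11 and 5, without 24 h 45, 6 and 5, and without 48 h 64, 4 and 6, with 1 for the average in each case. Without 6 h they were 192 for APOB-Hs3, 461 for APOB-Hs4 and 50 for the average.

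In liver each siRNA was set against the other 2. These contrasts are therefore not independent, and a difference in a single group also appears with the opposite sign in the contrasts of the others. Livers given APOB-Hs1 had less Dbp, a transcription factor driven by the circadian clock (-3.15, SE 0.487, adjusted p = 0.0295), less Upp2, a uridine phosphorylase (-2.31, 0.00942), less Bivm (-2.10, 1.26e-05) and less Thrsp, a regulator of lipogenesis (-1.53, 0.0435). They had more Tsc22d1 (1.70, 0.0231) and more Cdkn1a, which encodes the cell cycle inhibitor p21 (1.41, 0.0295). Livers given APOB-Hs4 had less Ilk (-1.82, SE 0.069, adjusted p = 6.26e-07), less Tsc22d1 (-2.0, 0.0102) and less Wdr55 (-0.98, 0.000178), and more of the interferon-induced or myeloid genes Slfn4 (1.23, 0.00375) and Ifi27 (1.07, 0.00375). The 4 genes called with APOB-Hs3 were all higher, Bivm (1.25, 0.00156), Ilk (1.10, 0.000141), Atg9a (0.94, 0.028) and 5430403G16Rik (0.67), and the first 3 of them fell with APOB-Hs1 or APOB-Hs4.

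With APOB-Hs1 68 genes differed (52 lower, 16 higher), with APOB-Hs3 4 and with APOB-Hs4 51 (27, 24). The interferon response was lower with APOB-Hs1 (29 genes, median -0.203, adjusted p = 1.33e-08, lost at adjusted p = 0.226 with an estimated correlation), where Ifit2 (-0.50, 0.039) was lower over all genes and 10 were lower and 1 higher adjusted over the list alone, among them Usp18 (-0.89) and Irf7 (-0.51). It was higher with APOB-Hs4 (median 0.278, adjusted p = 1.32e-12, lost at adjusted p = 0.349 with an estimated correlation), where Ifi27, Ifi44 (0.71), Ifit2 (0.57) and Oas2 (0.51) passed over all genes and 13 were higher and 1 lower adjusted over the list alone. Each group is part of the reference of the other, so opposite signs of a list with APOB-Hs1 and APOB-Hs4 are not separate results. Kupffer cell and macrophage markers followed the same order, with a median of -0.281 with APOB-Hs1 (17 genes, adjusted p = 2.78e-06, lost at 0.206 with an estimated correlation) and 0.212 with APOB-Hs4 (0.000389, lost at 0.36). Limma called 0 of these 17 markers over all genes in either group, with 6 lower unadjusted and 4 lower adjusted over the list alone with APOB-Hs1, and 8 higher and 1 lower unadjusted and 6 higher adjusted over the list alone with APOB-Hs4. The 4 red blood cell genes had a median of 0.62 with APOB-Hs1 (0.000638, lost at adjusted p = 0.226 with an estimated correlation), 4 of them higher adjusted over the list alone, and of -0.55 with APOB-Hs4 (0.00199, lost at 0.36), 1 of them lower adjusted over the list alone; limma called 0 over all genes, with 4 and 2 unadjusted.

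The remaining lists called in liver were as follows, each with its adjusted p by camera and, after it, the adjusted p with an estimated correlation, under which none held. With APOB-Hs1 lower medians were found for xenobiotic metabolism (-0.099, 0.000904 and 0.226), fatty acid synthesis (-0.165, 0.0099 and 0.485), the cell cycle (-0.085, 0.0141 and 0.37), lipoproteins (-0.046, 0.0148 and 0.206) and the acute phase (-0.042, 0.0172 and 0.206). Higher medians were found for the unfolded protein response (0.171, 0.0148 and 0.536), cholesterol synthesis (0.179, 0.0262 and 0.691) and fatty acid oxidation (0.06, 0.03 and 0.651). Adjusted over the list alone, 5 of 25 xenobiotic genes were lower, among them Gsta1 (-2.17), 2 of 20 fatty acid synthesis genes, 4 of 28 acute phase genes, among them Saa3 (-1.52) and Saa1 (-0.95), and 2 of 24 fatty acid oxidation genes were higher. The unfolded protein response had 1 higher and 1 lower, and cholesterol synthesis, the cell cycle and lipoproteins had 0 by limma, with 3 higher, 6 lower and 4 lower unadjusted. Over all genes the calls in these 8 lists were Thrsp, lower, and Chac1 of the unfolded protein response, higher (0.87, 0.0414). With APOB-Hs3 cholesterol synthesis (-0.272, 2.11e-05 and 0.794) and stellate cell markers (-0.116, 0.0304 and 0.794) were lower, and xenobiotic metabolism (0.111, 0.000924 and 0.794) and the cell cycle (0.062, 0.0304 and 0.794) were higher. With APOB-Hs4 stellate cell markers (0.173, 0.00124 and 0.515), fatty acid synthesis (0.19, 0.0133 and 0.515) and the acute phase (0.037, 0.0406 and 0.349, lost at 0.0658 after quantile normalization) were higher. Limma called 0 members of these 7 lists over all genes. Adjusted over the list alone, 3 xenobiotic and 2 cell cycle genes were higher with APOB-Hs3, and 1 fatty acid synthesis gene, Thrsp (1.07), and 1 acute phase gene, Saa3 (1.35), were higher with APOB-Hs4, while at an unadjusted p under 0.05 there were also 4 lower cholesterol synthesis and 2 lower stellate cell genes with APOB-Hs3 and 4 higher stellate cell genes with APOB-Hs4.

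Lists of miR-122 targets, let-7 targets, hepatocyte genes, lymphocytes, neutrophils, cholangiocytes and liver endothelial cells passed in no contrast of any system, and in liver with APOB-Hs1 their adjusted p was 0.936, 0.45, 0.68, 0.313, 0.234, 0.11 and 0.59. Over all systems 26 of 231 list tests passed and 0 with an estimated correlation, where the lowest adjusted p was 0.206 by camera of limma. Median, mean and test differed in sign in 40 list tests, and in 0 of those that passed. The liver counts rested on single livers: for APOB-Hs1 the count was 7 and 39 without its own liver 1 and 3, 38, 27 and 15 without APOB-Hs3 liver 1, 2 and 3, and 467, 21 and 13 without APOB-Hs4 liver 1, 2 and 3. For APOB-Hs4 it was 164, 9 and 10 without its own liver 1, 2 and 3, 20, 32 and 32 without APOB-Hs1 liver 1, 2 and 3, and 25 and 23 without APOB-Hs3 liver 2 and 3. For APOB-Hs3 it was 2 without APOB-Hs1 liver 3, any APOB-Hs3 liver, or APOB-Hs4 liver 1 or 2.

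The next question was whether an siRNA left the same signature in HUH7 and PLC/PRF/5. Across 17836 genes the mean Pearson r between the lines was 0.494 for the same siRNA (range 0.34 to 0.594) and -0.081 for different siRNAs (highest 0.075), with an exact permutation p of 0.000198, one-sided, the smallest that 5040 assignments allow. The mean of the mismatched r is drawn below 0 by construction, and genes are not independent replicates. Measured against the other siRNAs, 169 genes were lower in both lines with APOB-Hs1 (7.98 were expected if the lines were independent), 106 with APOB-Hs2 (2.37), 186 with APOB-Hs3 (6.14), 83 with APOB-Hs4 (2.35), 77 with Apob-Mm2 (2.24) and 100 with RAD18 (2.63). Most calls fell on brighter genes, which raises the number expected: among the 8130 genes above the median level in both lines, the numbers were 156 (11.7), 100 (3.40), 177 (10.2), 72 (3.08), 71 (3.59) and 85 (3.54) in the same order. Of the mismatched siRNAs, APOB-Hs3 in HUH7 and APOB-Hs2 in PLC/PRF/5 also shared more than expected over all genes (11 and 4.19 expected, Fisher adjusted p = 0.0231, or 10 and 6.33 among brighter genes). For Apob-Mm1 limma called 3 genes lower in HUH7 and 0 in PLC/PRF/5. Shared genes, with the difference from mock in HUH7 and then PLC/PRF/5, included NSF (-2.0 and -2.74) and the repair polymerase gene POLB (-1.50 and -2.20) with APOB-Hs1, PRXL2C (-0.98 and -1.70) with APOB-Hs2, the liver-enriched transcription factor gene CREB3L3 (-1.23 and -1.72) with APOB-Hs3 and TMEM106C (-1.08 and -1.62) with RAD18.

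**Figure D2:**
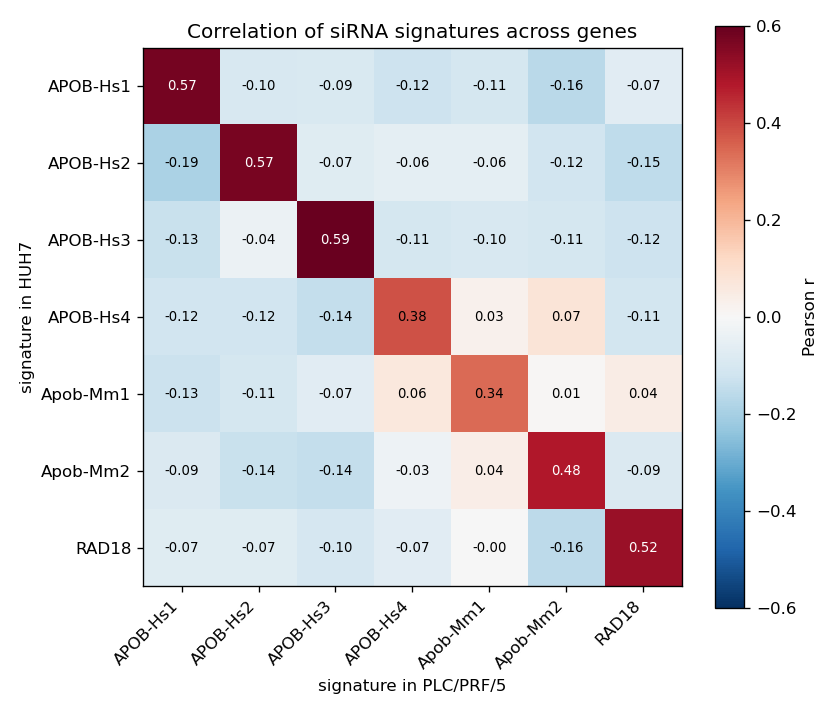
Pearson r across genes between the signature of each siRNA in HUH7 (vertical) and in PLC/PRF/5 (horizontal), each taken against the mean of the other siRNAs. The diagonal runs from 0.34 to 0.594, and the highest value off it is 0.075.

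Across species and between culture and animal, the same siRNA was compared for APOB-Hs1, APOB-Hs3 and APOB-Hs4. Bivm and Nomo1 were lower with APOB-Hs1 in all 4 systems: BIVM by -0.70 in HUH7, -0.61 in PLC/PRF/5, -2.37 in Hepa1-6 and -2.10 in liver, and NOMO1 by -0.96, -1.53, -1.23 and -0.98. ILK (-0.48, -2.52, -1.88 and -1.82) and ATG9A (-0.81, -1.44, -1.24 and -0.91) were lower with APOB-Hs4 in all 4. With APOB-Hs3 the phosphatase gene PTPRJ (-1.0, -1.0 and -0.76) and the RNA-binding gene RC3H2 (-0.53, -0.84 and -0.80) were lower in the 3 cell lines, as 2 of 9 such genes. Genes lower in both systems numbered 52, 39 and 27 for the 3 siRNAs in HUH7 and Hepa1-6 (11.6, 6.60 and 6.64 expected), or 49, 37 and 24 of 5964 genes above the median level in both (13.5, 9.78 and 8.18). They numbered 20, 17 and 21 in PLC/PRF/5 and Hepa1-6 (2.74, 2.34 and 3.14), or 20, 17 and 21 of 5935 brighter genes (2.95, 3.59 and 4.21), and 17 and 8 for APOB-Hs1 and APOB-Hs4 in Hepa1-6 and liver (0.906 and 0.55). HUH7 and liver shared 5 and 3 for APOB-Hs1 and APOB-Hs4 (1.53 and 0.437; Fisher adjusted p = 0.0765 for each), and PLC/PRF/5 and liver shared 4 and 2 (0.361 and 0.206; 0.00399 and 0.0801), so 3 of these 4 did not pass. Of the mismatched siRNAs, APOB-Hs1 in HUH7 and APOB-Hs3 in Hepa1-6 also shared more than expected (21 and 9.42 expected, 0.0011, or 18 and 13.4 among brighter genes). With APOB-Hs3 limma called no gene lower in liver, with 1824 genes at an unadjusted p under 0.05 in either direction. Mean matched r was 0.122 for HUH7 and Hepa1-6, 0.153 for PLC/PRF/5 and Hepa1-6, 0.086 for Hepa1-6 and liver and 0.038 for PLC/PRF/5 and liver, each with an exact permutation p of 0.167, the smallest that 6 assignments allow, and 0.034 for HUH7 and liver (exact p = 0.333), all one-sided. These designs cannot reach 0.05.

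**Figure D3:**
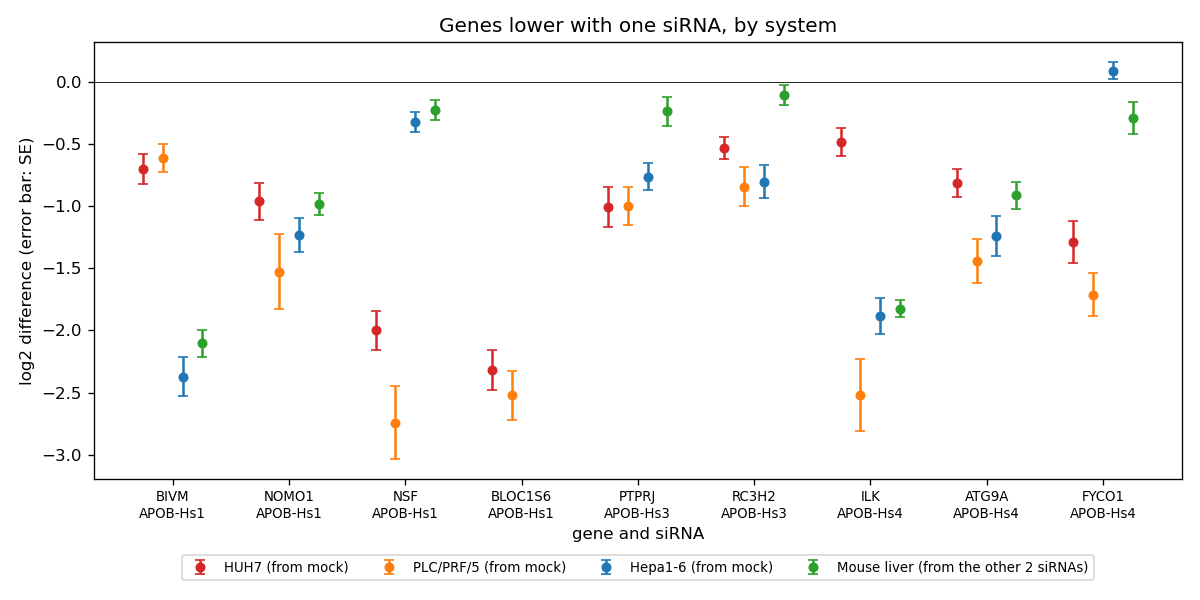
Log2 difference with its SE in each system for genes lower with one siRNA in several systems, against mock in the cell lines and against the other 2 siRNAs in liver; the genes were chosen after their values were seen. BIVM and NOMO1 (APOB-Hs1) and ILK and ATG9A (APOB-Hs4) lie below 0 in all 4 systems, and FYCO1 is not lower in Hepa1-6.

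Whether a response differed between HUH7 and PLC/PRF/5 was tested directly as an interaction. GALNT5 fell more in HUH7 than in PLC/PRF/5 with APOB-Hs1 (-2.21 and -0.24, difference -1.97, SE 0.304, adjusted p = 0.00371). ILK fell more in PLC/PRF/5 with APOB-Hs4 (difference 2.13, SE 0.342, 0.00823), as did the potassium channel gene KCNK1 with Apob-Mm2 (-0.13 and -1.21, difference 1.15, 0.0084), and with the RAD18 siRNA the prostaglandin receptor gene PTGER3 (0.08 and -1.34, difference 1.47, 0.0337) and RAD18 itself (difference 1.48, 0.0369). These 5 were the genes called among 17836. With APOB-Hs2, APOB-Hs3 and Apob-Mm1 limma called 0 genes, with 602, 592 and 260 at an unadjusted p under 0.05, and 1 for APOB-Hs2 without 6 h. Each of these unadjusted counts is a smaller share of the genes than the 0.05 expected with no difference. Without 12 h none of the 5 was called, without 48 h the counts for APOB-Hs4 and RAD18 were 0, and without 6 h they were 0 for Apob-Mm2 and 1 for RAD18.

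The course over time was read in genes called lower in the other human line. In HUH7 their mean difference from the other siRNAs was -0.18 at 6 h, -0.39 at 12 h, -0.57 at 24 h and -0.64 at 48 h (SD 0.141, 0.204, 0.125 and 0.12, n = 6 siRNAs), lower at the last time than at the first for 6 of 6 (mean -0.45, two-sided exact p = 0.0312, the smallest that 64 sign patterns allow). In PLC/PRF/5 it was -0.15, -0.35 and -0.67 at 6, 12 and 48 h (SD 0.054, 0.098 and 0.197, n = 7 siRNAs; mean change -0.52, two-sided exact p = 0.0156, the smallest that 128 patterns allow). The value for Apob-Mm1 in PLC/PRF/5 rested on 3 genes, and without it the mean change was -0.49 (exact p = 0.0312).

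**Figure D4:**
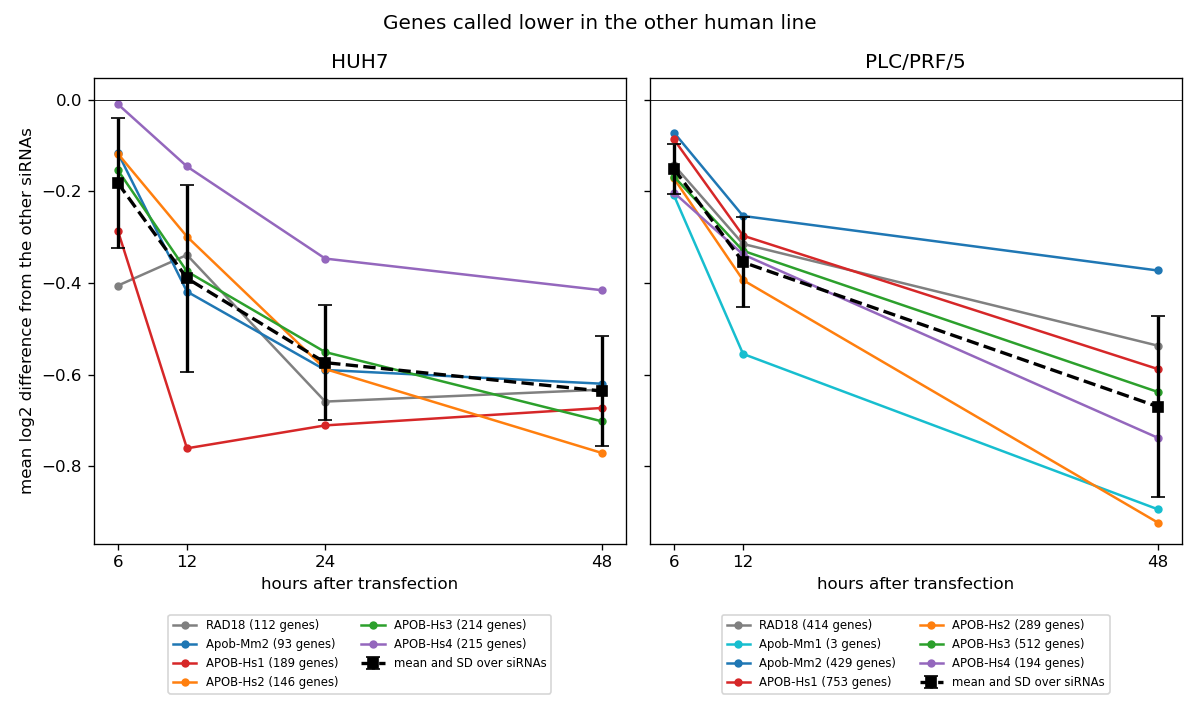
Mean log2 difference from the other siRNAs, by hours after transfection, of the genes called lower for each siRNA in the other human line, with the mean and SD over siRNAs. The mean goes from -0.18 at 6 h to -0.64 at 48 h in HUH7 and from -0.15 to -0.67 in PLC/PRF/5.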

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

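The tests of signal level and of response ratio below were chosen only after the differences were seen; the test of the difference itself was planned. For 5 genes the response to an siRNA differed between HUH7 and PLC/PRF/5 by limma's interaction test, which is what put them here. As the HUH7 difference from mock minus the PLC/PRF/5 difference, the values were -1.97 for GALNT5 with APOB-Hs1 (SE 0.304), 2.13 for ILK with APOB-Hs4 (0.342), 1.15 for KCNK1 with Apob-Mm2 (0.185), 1.47 for PTGER3 with the RAD18 siRNA (0.255) and 1.48 for RAD18 with the RAD18 siRNA (0.27). Without 12 h all 5 ended, with differences of -1.75 for GALNT5 (SE 0.449), 2.02 for ILK (0.54), 1.18 for KCNK1 (0.237), 1.32 for PTGER3 (0.354) and 1.28 for RAD18 (0.375). Without 48 h the calls of ILK (1.92, SE 0.319, adjusted p = 0.094), PTGER3 (1.45, 0.266, 0.565) and RAD18 (1.28, 0.322, 0.966) ended, and without 6 h those of KCNK1 (1.07, 0.257, 0.874) and PTGER3 (1.64, 0.269, 0.0558). Where a call ended the size moved by less than its SE, in fits with fewer arrays.

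GALNT5, KCNK1 and PTGER3 each fell only in the line with the higher mock level. Their mock log2 levels in HUH7 and PLC/PRF/5 were 8.13 and 4.11, 2.98 and 6.02, and 2.69 and 7.21. In the line without the fall the highest of the 3 ranked at percentile 19.7 of all genes, which is consistent with a signal near the floor, where a further fall would not show on the array. A difference in how these transcripts respond to the siRNA was not tested apart from that and stays open.

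The mock levels of ILK and RAD18 were well above the floor in both lines (log2 log2 10.49 and 10.17, and 7.99 and 7.73), and the lower of them ranked at percentile 64.8 of all genes in HUH7, which argues against a floor that hides a fall in HUH7. For ILK the ratio of the HUH7 to the PLC/PRF/5 difference was 0.192, while the other 34 genes called lower in PLC/PRF/5 with APOB-Hs4, whatever they did in HUH7, had a median of 0.471 (SD 0.233), and 5 of the 34 had a ratio as low. Since ILK was picked for its difference between the lines, a low ratio was given by that choice, and a weaker action of APOB-Hs4 on all its genes in HUH7 stays open. Another transcript form or a probe match in HUH7 stays open too, since 1 probe set measured ILK and no sequence was at hand. With its siRNA RAD18 stood at log2 4.03 at 12 and 48 h in PLC/PRF/5, as low as the level taken above as near the floor. If that level is near the floor, the fall of RAD18 there and the difference of 1.48 are understated. No floor was measured, however, and other genes read lower, such as PTGER3 at 2.69 in HUH7 mock. The ratio of 0.61, beside a median of 0.706 over 41 genes (SD 0.267), therefore cannot be read as exact. A weaker action of the RAD18 siRNA in HUH7 and a difference between the lines in RAD18 turnover both stay open.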

How the results depend on the processing

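The alternatives that left out the APOB-Hs1 array of 12 h in HUH7, the APOB-Hs2 and APOB-Hs4 arrays of 48 h in PLC/PRF/5, or siRNAs with under 20 genes in the course were chosen after seeing the data; the others were planned. Under the alternatives no named gene, list or main difference that was called took the opposite sign, but the balance of APOB-Hs4 in HUH7 turned from 96 lower and 187 higher to 161 and 135 under quantile normalization. Among all called genes up to 6 per comparison had the opposite sign, 6 for APOB-Hs3 in HUH7 with the other siRNAs as the reference and 3 for APOB-Hs2 with the mean of all probe sets. Of 613 main values and counts 410 kept their side of the threshold or, for counts, stayed within 1.5 times. Of the rest, 191 counts moved beyond 1.5 times, 8 calls were lost and 4 gained. Of 2703 values of single genes and lists 2021 kept their side of the threshold, 660 lost their call and 22 gained one. The falls of APOB and RAD18 kept their side of the threshold under quantile normalization and the mean of all probe sets. The similarity of HUH7 and PLC/PRF/5 did so under quantile normalization, Spearman correlation, omission of APOB and RAD18, and with the dimmer genes left out. The course did so with the 100 most negative genes and, in PLC/PRF/5, without siRNAs with under 20 genes, the settings tried for it. Except where a smaller number of genes or arrays is the alternative itself, the cause was not tested. Analyses of hexamers in 3′ untranslated regions were not run, together with their alternatives. Signal over background could not be read without detection calls, so small changes of dim genes stay uncertain.

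Without a time term HUH7 gave 179 genes for APOB-Hs1, 71 for APOB-Hs2, 104 for APOB-Hs3, 25 for APOB-Hs4, 36 for Apob-Mm2, 50 for RAD18, 1 for the average and 184 for the human APOB siRNAs against the others. PLC/PRF/5 gave 55, 32, 22, 18, 10, 24, 0 and 16 in that order. Hepa1-6 gave 80, 43 and 43 for APOB-Hs1, APOB-Hs3 and APOB-Hs4 and 0 for the average. With only 1 siRNA and mock in the fit, which has fewer arrays, HUH7 gave 4, 1, 3, 0, 2 and 4 for APOB-Hs1 to APOB-Hs4, Apob-Mm2 and RAD18, PLC/PRF/5 gave 1, 0, 1, 2, 3 and 0, and Hepa1-6 gave 49, 0 and 5. With the mean of the other siRNAs as the reference, which averages more arrays, HUH7 gave 1111 for APOB-Hs1, 660 for APOB-Hs3, 467 for APOB-Hs4, 4 for Apob-Mm1, 776 for Apob-Mm2 and 511 for RAD18, PLC/PRF/5 gave 250, 168, 223 and 229 for APOB-Hs1 to APOB-Hs4, 101 for Apob-Mm2 and 131 for RAD18, and Hepa1-6 gave 743, 447 and 935.

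With the dimmer genes left out, which tests fewer genes, HUH7 gave 616 for APOB-Hs3, 536 for APOB-Hs4, 1 for Apob-Mm1, 383 for Apob-Mm2 and 66 for the average. PLC/PRF/5 gave 85 for APOB-Hs3, 41 for Apob-Mm2 and 116 for the human APOB siRNAs. Hepa1-6 gave 343, 240 and 622 and 64 for the average, liver gave 129 for APOB-Hs1 and 7 for APOB-Hs3, and the interaction between the lines gave 0 for APOB-Hs1, 0 for Apob-Mm2 and 1 for RAD18. Trend and robust settings of limma gave 1 for Apob-Mm1 in HUH7, 0 for the average in PLC/PRF/5, 304, 249 and 594 in Hepa1-6 with 71 for the average, and 196, 20 and 102 in liver. Quantile normalization gave 1 for Apob-Mm1 in HUH7 and 13 for the average in Hepa1-6, and the number of lists called went from 2 to 1 for the average in PLC/PRF/5 (xenobiotic metabolism lost, adjusted p = 0.0744). In Hepa1-6 it went from 1 to 0 for the average (small RNA machinery lost, 0.0906), from 1 to 3 for APOB-Hs1 (cholesterol synthesis, 0.00883, and xenobiotic metabolism, 0.0383, gained) and from 0 to 1 for APOB-Hs3 (cell cycle, 0.0219). In liver it stayed at 6 for APOB-Hs4, with the acute phase lost (0.0658) and fatty acid oxidation gained (0.0452). With an estimated correlation camera called 0 lists everywhere, in place of 1, 2, 1, 1, 11, 4 and 6. Without the APOB-Hs1 array of 12 h HUH7 gave 512 for APOB-Hs4, 1 for Apob-Mm1 and 68 for the average. Without the APOB-Hs2 and APOB-Hs4 arrays of 48 h PLC/PRF/5 gave 168 for APOB-Hs1, 111 for APOB-Hs3, 48 for Apob-Mm2 and 69 for RAD18.

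In liver the number in the label as a block gave 143 for APOB-Hs1 and 33 for APOB-Hs4, while the count for APOB-Hs3 stayed within 1.5 times. The labels do not say that the numbers pair the livers, and residual correlation of livers with the same number ran from -0.148 to 0.19. Against 1 siRNA alone, APOB-Hs1 gave 13 against APOB-Hs3 and 116 against APOB-Hs4, APOB-Hs3 gave 13 against APOB-Hs1 and 19 against APOB-Hs4, and APOB-Hs4 gave 116 against APOB-Hs1 and 19 against APOB-Hs3.

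Leaving out each time point or liver in turn gave these ranges. In HUH7 they were 105 to 652 genes for APOB-Hs1, 22 to 566 for APOB-Hs2, 10 to 701 for APOB-Hs3, 7 to 310 for APOB-Hs4, 0 to 3 for Apob-Mm1, 13 to 322 for Apob-Mm2, 24 to 198 for RAD18, 0 to 53 for the average and 53 to 923 for the human APOB siRNAs, lowest without 24 h except for Apob-Mm1 and highest without 6 h. APOB itself ranged from -2.10 to -1.42 with APOB-Hs3, -1.58 to -1.08 with Apob-Mm1 and -1.12 to -0.66 with Apob-Mm2. In PLC/PRF/5 the counts were 4 to 118, 0 to 105, 0 to 53 and 1 to 29 for APOB-Hs1 to APOB-Hs4, 0 to 1 for Apob-Mm1, 1 to 49 for Apob-Mm2, 1 to 31 for RAD18, 0 to 1 for the average and 0 to 76 for the human APOB siRNAs. APOB there ranged from -3.24 to -2.26, -3.83 to -2.76, -3.37 to -1.83 and -3.54 to -3.10 with APOB-Hs1 to APOB-Hs4, -3.05 to -2.01 with Apob-Mm1 and -2.51 to -1.16 with Apob-Mm2. In Hepa1-6 the counts were 37 to 201, 4 to 192 and 5 to 461, and 1 to 50 for the average. In liver they were 7 (without APOB-Hs1 liver 1) to 467 (without APOB-Hs4 liver 1) for APOB-Hs1, 2 to 6 for APOB-Hs3 and 9 (without APOB-Hs4 liver 2) to 164 (without APOB-Hs4 liver 1) for APOB-Hs4. The interaction gave 0 to 1 for APOB-Hs1, APOB-Hs2, APOB-Hs4, Apob-Mm2 and RAD18.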

Other observations

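The tests of explanations in this part, counts of other splits included, were chosen only after the result was seen, and so were the genes named here and the clock genes. Single transcripts of the small RNA pathway were lower with some siRNAs, while the list of 14 such genes passed in no human contrast (adjusted p = 0.51 in HUH7 and 0.101 in PLC/PRF/5 for the human APOB siRNAs against the others). XPO5 fell with Apob-Mm2 in HUH7 (-1.26, adjusted p = 1.34e-05) and PLC/PRF/5 (-1.80, 0.000126), and DICER1, which encodes the nuclease that matures microRNAs, fell with APOB-Hs1 in both (-0.95, 1.87e-05, and -1.31, 0.00591). TNRC6B fell with APOB-Hs3 in both (-0.69, 0.00416, and -1.13, 0.038) and with APOB-Hs2 in PLC/PRF/5 (-1.07, 0.0493), and rose with Apob-Mm2 in HUH7 (0.56, 0.0335). POLR3G fell with APOB-Hs3 in both lines (-1.19, 2.8e-05, and -1.44, 0.0348) and with the RAD18 siRNA in HUH7 (-1.32, 3.02e-06), where PLC/PRF/5 gave -1.34 (0.058). TXNRD1, a thioredoxin reductase of the redox defence, fell with the RAD18 siRNA in both (-0.96, 6.14e-07, and -1.09, 0.00291). RPL41 lay above mock with all 7 siRNAs in HUH7 (0.25 to 1.09, past the test for 4) and in PLC/PRF/5 (0.24 to 0.89, none past the test); all share the same mock arrays.

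Livers given APOB-Hs1 stood apart in the circadian clock. Of 12 genes of the arm that peaks with Dbp, 11 were below the other livers, 3 past the test over all genes (Dbp -3.15, Tef -1.13 and Cry2 -0.60) and 10 adjusted over the list alone. The 5 genes of the opposite arm, among them Arntl (1.37) and Nfil3 (1.32), all lay above, 0 by limma over all genes and 5 adjusted over the list alone and so at an unadjusted p under 0.05. Since the 17 genes were listed with the values in view, counts over the list alone are not independent evidence, and the clock gene Bhlhb2 (-0.99, adjusted p = 0.241) was not in the list. The gap between the arms was -1.75 (SE 0.454), and per liver it was -1.47, -1.17 and -0.37 with APOB-Hs1, 0.36, 0.52 and 0.70 with APOB-Hs3 and -0.08, 1.76 and 1.19 with APOB-Hs4.

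Livers of 1 group taken at another time of day could move the arms apart in this way (gap -1.75), but the gap rests on genes listed with their values in view, so it is no test of that, and the labels record no time of day. It stays open. Direct action of APOB-Hs1 on clock genes is not settled by Hepa1-6. The gap there was -0.037 (SE 0.058), so on average over the time points the arms did not move apart in those cells. Clock was higher there (0.36, limma adjusted p = 0.109, or 0.0254 over the list alone) as in liver (0.44). It was the only listed gene to pass over the list alone. Nr1d1 went the other way, at 0.355 in Hepa1-6 and -0.955 in liver. Of the 12 genes of the Dbp arm 7 lay below mock in Hepa1-6, as did 2 of the 5 of the opposite arm. A shift in the timing of the clock could be missed by a mean over times, so direct action stays open. Livers given APOB-Hs4 had the lowest mean Apob and a gap of 0.43 from those given APOB-Hs3 (SE 0.524), against -1.53 for APOB-Hs1 and APOB-Hs3. These values cannot decide whether the depth of the Apob fall plays a part. No untreated liver was listed, no liver difference in Apob passed the test, and the clock genes were listed with liver values in view. That explanation stays open. An effect of feeding, handling or illness on the clock of these livers was not tested and stays open. Thrsp, Upp2 and other liver differences may share that source, so the liver data alone cannot assign them to the siRNA. The falls of Bivm and Nomo1 with APOB-Hs1 and of Ilk and Atg9a with APOB-Hs4 were seen in all 4 systems. For these genes that argues against a source confined to the livers.

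Genes lowered by 1 siRNA in human and mouse cells may be direct hits on conserved transcripts. With calls taken against mock, which keeps genes that fall with every siRNA, the same siRNA shared at least 8.36 times the number expected of independent genes, while different siRNAs shared at most 6.91 times. That argues against genes that are called lower whatever the siRNA as the whole cause, though they may add to it, since different siRNAs also shared more than expected. HUH7 and Hepa1-6 shared 39 genes for the same siRNA, a ratio of 9.93 over 3 comparisons, and 18 for different siRNAs (2.17 over 6), and PLC/PRF/5 and Hepa1-6 shared 22 (21.2) and 7 (3.29). APOB was left out. Whether these transcripts carry matches to the siRNA seed stays open, since neither siRNA nor transcript sequences were at hand.

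Other splits of the same arrays into groups of the same sizes were counted for each comparison. Each siRNA and mock were measured at the same times, so the real split was compared with those that swap siRNA and mock within time points, 8 in HUH7 and Hepa1-6 and 4 in PLC/PRF/5, which are too few for a share under 0.05. In HUH7 the real value was the 1 of 8 for APOB-Hs1 (452 genes, highest other 212), APOB-Hs2 (424 and 67), APOB-Hs3 (400 and 94), APOB-Hs4 (283 and 3), Apob-Mm2 (231 and 102) and RAD18 (168 and 0). In Hepa1-6 it was the 1 of 8 for APOB-Hs1 (165 and 0), APOB-Hs3 (125 and 0) and APOB-Hs4 (259 and 0). In PLC/PRF/5 it was the 1 of 4 for APOB-Hs1 (107), APOB-Hs2 (63), APOB-Hs3 (52), APOB-Hs4 (36), Apob-Mm2 (25) and RAD18 (42), with 0 as the highest other. For Apob-Mm1 limma called 0 genes in both lines (631 and 358 unadjusted), so all 8 and all 4 splits were as large and the count decides nothing. The splits that mix times, which make up the rest of 35 in HUH7 and Hepa1-6 and of 10 in PLC/PRF/5, reached at most 101 for APOB-Hs3 and 2 for RAD18 in HUH7 and 1 for APOB-Hs1 in Hepa1-6, and for the others no more than the splits within times.

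For contrasts over several siRNAs the picture differed. For the average against mock, with the mock label swapped within time points, 6 of 100 splits were as large in HUH7 (36 genes, highest other 315) and 8 of 100 in PLC/PRF/5 (1 and 100), so chance cannot be excluded for these counts, and 2 of 100 in Hepa1-6 (8 and 350), a share under 0.05. The count says nothing of the 1 gene in PLC/PRF/5, which was APOB, at -3.27 to -1.82 with the 6 siRNAs named for it. The swaps also give the mock label to arrays that carry siRNA effects, so they are not a reference without any change. The Hepa1-6 share is also unadjusted over the contrasts counted, so it does not exclude chance. The Hepa1-6 count was 1 without 12, 24 or 48 h. For the human APOB siRNAs against the others 12 of 35 were as large in HUH7 (700 and 1223) and 29 of 35 in PLC/PRF/5 (70 and 229), so chance cannot be excluded for these counts. In liver 2 of 100 were as large for APOB-Hs1 (68 and 263) and 3 of 100 for APOB-Hs4 (51 and 68). These shares are under 0.05 but unadjusted over the contrasts, and the livers carry siRNA effects, so they do not exclude chance. The counts ran from 7 to 467 and from 9 to 164 without single livers. For APOB-Hs3 the share was 9 of 100 (4 and 64), where chance cannot be excluded. Splits with several times the real count, as for the averages in all 3 lines, the human APOB siRNAs in PLC/PRF/5, and APOB-Hs1 and APOB-Hs3 in liver, point to a structure of the samples. What it is was not tested, and the effects of single siRNAs on the arrays that change groups could account for it.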
